A study of Homo sapiens with 2 samples.

How the data were processed

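Total RNA from HT-29 cells, 1 flask with bacteria and 1 without, was labelled as biotinylated cRNA and hybridised to Illumina expression arrays, per the labels' protocols. GenomeStudio is the software named in the submitters' processing notes. The deposited table holds 1 intensity per probe and array on a linear scale, and no further step is given in the sources used here. The values themselves show background subtraction, since 27.7% of the control array and 27.2% of the incubated array lie below 0. Both deposited columns have a mean of 232 units, as scaling to a common mean would give. Their medians are 5.32 and 5.79 units. Detection p-values and bead-level values were not analysed here. Growth medium was removed and the cells washed before bacteria were added, per the labels' protocols, which do not say whether the control flask was handled in the same way.

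The rules below were set before the data were examined. The deposited values were to be kept if the 2 columns agreed within 5% at 6 percentiles from the 50th to the 95th. They differed by 8.74% at the 50th, so the 2 columns were quantile normalized. Quantile normalization removes any difference in overall distribution, so changes are relative to the whole array. The background floor of each array was the 95th percentile of 585 probes of olfactory receptor, taste receptor and keratin-associated protein genes, which a colon epithelial line is not expected to express. The difference between arrays of those probes had a robust SD of 4.05 units. It describes the spread across silent probes on 1 pair of arrays and is not an error between replicates. A gene was measured where both values exceeded the floor. A gene above the floor on 1 array gave a bound against the floor of the other, written as "at least". The number of arrays limits the precision.

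Gene names came from the platform annotation. Of the probes, 30112 had 1 gene symbol, 8 had several and 17197 had none here and stayed unnamed. Through their gene identifiers 30073 probes matched the gene table of the human reference (GRCh38.p14), used for names only. No genome build is given for the array data, so no coordinates are printed. Each of the 20046 genes was represented by its probe with the highest mean log2 value over both arrays. Probes of one gene can disagree in size and in sign, and a single probe can measure one transcript form.

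With 1 array per group no test across samples exists. Genes were counted by size, at a log2 ratio of 1 (2-fold) or more. As a yardstick, the robust spread (scaled median absolute deviation) of log2 ratios was taken in 10 bins of mean intensity. It was 0.53 in the dimmest bin and 0.13 in the brightest and describes differences between genes, not between replicates. A total of 36 gene lists were fixed, 30 for pathways and functions and 6 for markers of cell types. For each list the median log2 ratio of its measured members was placed among 10000 random lists of the same size, matched on intensity bins. A percentile under 2.5 or over 97.5 is called outside the central 95%, as a description of these 2 arrays.

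Genes named in the text followed a fixed rule. It took the 15 highest and 15 lowest measured genes with characterised names, up to 4 members per list and direction that were at least 2-fold apart, the highest and lowest member of lists with none, and the 5 largest bounds in each direction. Genes named outside the rule were chosen after their values were seen, and the text says so.

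The procedure was tested on simulated data, in which 200 genes of these arrays were changed by known folds with additive noise taken from the silent probes and multiplicative noise taken from bright genes. Of 44 genes lowered 3-fold 95.5% were counted, as were 100% of 48 genes raised 3-fold, 6.00% of 50 genes raised 1.5-fold and 0% of 44 lowered 1.5-fold. Among 10620 unchanged simulated genes, 7 passed 2-fold. The simulated noise holds no difference between flasks and no probe effects that differ between arrays. The figure of 7 is therefore no estimate of false calls in the data. Of 100 simulated lists of randomly drawn genes without effect, 6 fell outside the central 95%. Their members varied independently, which the members of a pathway may not do.

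The alternatives tried were the deposited values, median centring, removal of a loess curve (fraction 0.3), floors at the 60th and 75th percentile of all probes, no floor, 50 units added before log2, the mean over measured probes and the probe with the smallest change. A limit of 100 units on the brighter array was added after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.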

Results

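Gene expression was measured in HT-29 cells, an established human colon adenocarcinoma line with epithelial features. One flask of cells was incubated for 3 hours with Bifidobacterium bifidum ATCC 29521, a strain of an anaerobic gut commensal, and 1 flask was kept without bacteria. Each flask gave 1 RNA sample and 1 Illumina expression array, so each group holds 1 sample. The study asked which genes differ in expression after contact with the bacterium. With 1 array per group the differences below compare these 2 RNA samples, have no replicate check and carry no p-value. Each array reported 47317 probes, of which 19930 lay above the background floor without bacteria and 20370 after incubation. The floor was 9.19 intensity units on the first array and 8.62 on the second. A total of 10860 genes were measured above the floor on both arrays, and the fold changes below refer to these unless a bound is named.

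Most genes differed little between the 2 samples. Of the measured genes, 92.3% lay within 1.5-fold, 68 were at least 2-fold higher after incubation and 48 were at least 2-fold lower. The highest ratios were those of ANGPTL4, an inhibitor of lipoprotein lipase, of PFKFB4, a regulator of glycolytic flux, of FOS, a subunit of the AP-1 transcription factor, and of BHLHE40, a transcriptional repressor. ANGPTL4 was 11.8-fold higher (92.7 against 1096 units, log2 ratio 3.56), PFKFB4 was 7.04-fold higher (112 against 787 units, log2 ratio 2.82), FOS was 5.88-fold higher (50.9 against 299 units, log2 ratio 2.56) and BHLHE40 was 4.53-fold higher (96.4 against 437 units, log2 ratio 2.18). The ANGPTL4 value rests on its brightest probe, since ANGPTL4 was 3.82-fold higher with the mean of its probes and 2.14-fold with the probe of smallest change. These 4 genes were the ones at least 4-fold higher by their brightest probe, and 0 measured genes were at least 4-fold lower. With 50 units added before log2, FOS (3.46-fold) and BHLHE40 (log2 ratio 1.73) came under 4-fold. The log2 ratios of genes of like intensity had a robust spread of 0.22 at the level of ANGPTL4 and PFKFB4, of 0.27 at that of FOS and of 0.24 at that of BHLHE40. Scaling changed the balance of the calls: the deposited values gave 94 genes higher and 36 lower, and median centring gave 90 and 39. Of the 116 genes at least 2-fold apart, 83 were dimmer than 100 units on both arrays, and among the brighter genes 27 were higher and 6 lower. With 50 units added before log2, which shrinks the ratios of dim genes by construction, 23 of the 37 genes at least 2-fold apart that the naming rule took came under 2-fold. The 14 others were ADM, ANGPTL4, ANKRD37, BHLHE40, DDIT4, EGR1, ELF3, ENO2, FOS, HK2, KDM3A, PDK4, PFKFB3 and PFKFB4, of which EGR1 alone was lower.

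**Figure D1:**
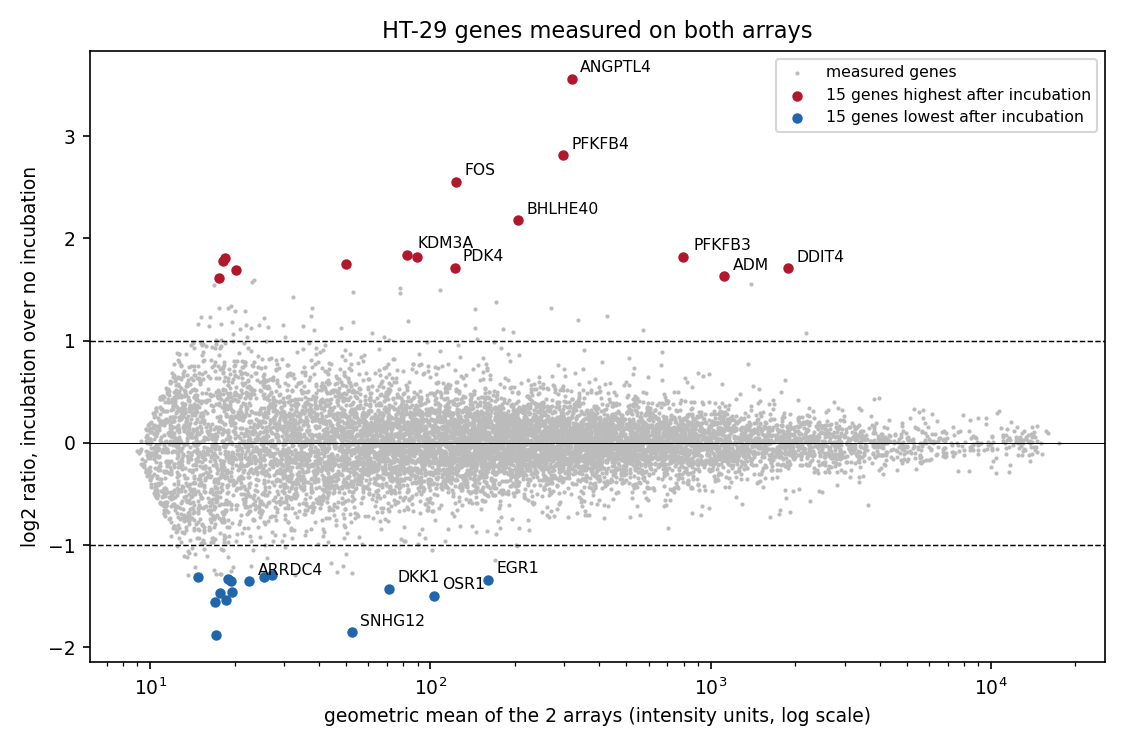
Log2 ratio of incubated over control cells (vertical axis) against the geometric mean intensity of the 2 arrays (horizontal log axis, intensity units) for the 10860 measured genes, 1 point per gene, with dashed lines at 2-fold. ANGPTL4 (3.56), PFKFB4 (2.82), FOS (2.56) and BHLHE40 (2.18) stand above the rest, and the cloud of ratios widens toward low intensities.

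Genes known to respond to low oxygen were higher after incubation as a group. Of 23 measured members of the hypoxia list, 22 had ratios above 0 and 6 were at least 2-fold higher, with a median log2 ratio of 0.43 that lay above all 10000 random lists matched on intensity. The 6 were ANGPTL4, BHLHE40, KDM3A, ANKRD37, DDIT4 and ADM. KDM3A, a histone demethylase, was 3.58-fold higher (43.5 against 156 units) and ANKRD37 was 3.53-fold higher (47.8 against 169 units). With 50 units added before log2, KDM3A was 2.20-fold and ANKRD37 2.24-fold higher. DDIT4, an inhibitor of mTORC1 signalling, was 3.26-fold higher (1047 against 3417 units), and ADM, which encodes the peptide hormone adrenomedullin, was 3.10-fold higher (635 against 1967 units). Smaller values, named after they were seen, were those of ZNF395 (1.99-fold higher), of VEGFA, the vascular growth factor (1.74-fold, with a second measured probe at a log2 ratio of 1.29), and of NDRG1 (1.71-fold). MXI1 and BNIP3 were also picked after their values were seen. MXI1 was the member with a negative ratio (log2 ratio -0.23), although 2 of its other probes were above the floor after incubation only. BNIP3, a mitochondrial protein of the same list, was dim on the control array (14.8 units) and below the floor after incubation.

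Glycolysis genes were also higher as a group. Of 20 measured members 18 had ratios above 0 and 5 were at least 2-fold higher, with a median log2 ratio of 0.21 that exceeded all 10000 matched random lists. Besides PFKFB4, its relative PFKFB3 was 3.53-fold higher (425 against 1500.0 units), hexokinase HK2 was 2.49-fold higher (170 against 424 units), enolase ENO2 was 2.30-fold higher (222 against 510 units), and the glucose transporter SLC2A1, named after its value was seen, was 2.10-fold higher (1514 against 3181 units). PDK4, a kinase that limits pyruvate entry into mitochondria, was 3.28-fold higher (67.3 against 221 units). The oxidative phosphorylation list had a median log2 ratio of -0.02 over 34 measured members, at percentile 28.7 of its random lists.

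**Figure D2:**
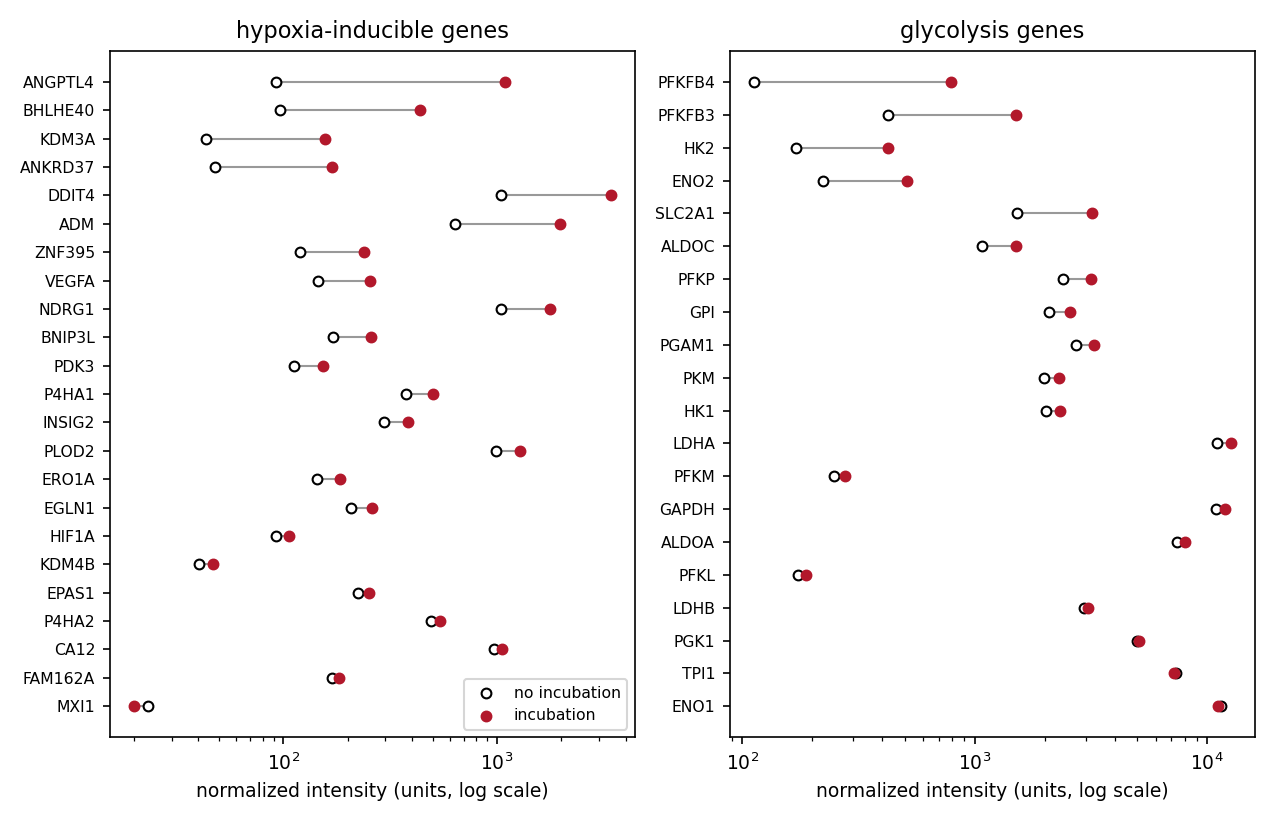
Quantile-normalized intensity (horizontal log axis, units) of each measured hypoxia-inducible gene (left) and glycolysis gene (right), open circles for the control array and filled circles for the incubated array, 1 array each. In the hypoxia panel 22 of 23 genes lie to the right after incubation, from ANGPTL4 (92.7 to 1096 units) down to small shifts, and in the glycolysis panel 18 of 20 do.

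The remaining genes among the 15 highest were of mixed function, and several were dim. FAM13A was 3.36-fold higher (27.2 against 91.4 units). PIGZ (3.50-fold), NAV1 (3.44-fold), the surface protease TMPRSS2 (3.23-fold) and PIK3IP1, an inhibitor of PI3-kinase (3.05-fold), all lay between 9.81 and 11.3 units on the control array. Their control values lie close to the floor, and the spread of log2 ratios among genes of their intensity was 0.43 to 0.53. Repeated probes of a gene bear on single ratios, although they share the RNA and the array. Of 16 genes at least 2-fold apart that had a second measured probe, 14 had a second probe of the same sign and 10 of at least 2-fold the same way. For FAM13A the second probe gave 3.32-fold, for PFKFB3 2.73-fold and for HK2 1.82-fold. For ANGPTL4 the other 2 probes gave 2.14-fold and 2.20-fold, well under the 11.8-fold of the brightest probe. Over all 2847 genes with 2 or more measured probes, the 2 brightest probes had the same sign in 64.6% (Wilson 95% interval 62.8 to 66.3). The interval treats genes as independent and does not measure variation between samples.

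The 15 lowest genes held signalling and transcription factor genes beside dim genes. OSR1, a zinc finger transcription factor, was 2.82-fold lower after incubation (172 against 61.1 units), the Wnt antagonist DKK1 was 2.69-fold lower (117 against 43.4 units) and EGR1, an immediate early transcription factor, was 2.53-fold lower (255 against 101 units). SNHG12, a non-coding host of small nucleolar RNAs, was 3.62-fold lower (99.5 against 27.5 units). ARRDC4, an arrestin-domain protein that limits glucose uptake, was 2.56-fold lower by its brightest probe (36.0 against 14.1 units) and 3.66-fold lower by its second. BDNF, a neurotrophin, was 2.75-fold lower (32.6 against 11.9 units), with a second measured probe at 2.60-fold. ARMC5, FAM242F, IGFBP5, MPHOSPH10P1, SNORD49A, PGBD3, KBTBD11, TXNL4B and CDC42EP3 were 2.45-fold to 3.67-fold lower, and each was under 43 units on the control array. MPHOSPH10P1 is a pseudogene whose probe may not tell it from related transcripts.

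Ribosome biogenesis genes were lower as a group, and all 26 measured members had ratios below 0. Their median log2 ratio was -0.28, below all 10000 matched random lists, and none was 2-fold apart. RRP9, a component of the U3 small nucleolar ribonucleoprotein, was 1.86-fold lower (124 against 66.9 units) and nucleolin NCL was nearly level (2455 against 2429 units). The ribosomal proteins themselves lay within the range of random lists: 43 measured members had a median log2 ratio of -0.01, with RPL37 highest (0.71) and RPS15 lowest (-0.22).

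Genes of amino acid supply and the integrated stress response, which ATF4 drives, were also lower as a group. The median log2 ratio was -0.21 over 29 measured members, below all 10000 random lists, with 22 below 0. Among members named after their values were seen, ATF4 was 1.52-fold lower by its brightest probe (4478 against 2944 units). Its second probe had a log2 ratio of -0.57, and a dim further probe one of 0.24. DDIT3, which encodes the stress factor CHOP and was also picked after its value was seen, was 1.76-fold lower (186 against 106 units). CHAC1, a glutathione-degrading ATF4 target, was below the floor after incubation and at least 3.25-fold lower. VLDLR, a lipoprotein receptor on the same list, was 2.49-fold higher (24.0 against 59.8 units). The oxidative stress list was lower by a small amount (median log2 ratio -0.09 over 27 members, percentile 1.35, from SLC7A11 at -0.37 to UGT1A6 at 0.36, whose other measured probes gave 0.17 and -0.18), and its call was lost with the mean of probes (-0.078). Endoplasmic reticulum stress genes (median 0.02, from DNAJC3 at -0.51 to HYOU1 at 0.21), heat shock genes (0.03, from HSF1 at -0.65 to HSPB8 at 0.72) and metallothioneins with zinc transporters (-0.02, from SLC30A1 at -0.56 to MT1E at 0.34) lay within the central 95% of their random lists. HSPB8 was dim (13.8 against 22.8 units).

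Inflammatory genes were not higher as a group after 3 hours. Of 34 listed chemokines and cytokines on the array, 17 were measured, with a median log2 ratio of -0.25 (percentile 0.420) and 11 below 0. CCL20, an epithelial chemokine, was lowest (36.2 against 18.1 units, just under 2-fold), CX3CL1 was highest (0.43), and CXCL8, named after its value was seen, had a log2 ratio of -0.25 (1147 against 963 units). The list's call was lost in 3 of 9 alternative settings. Interferon-stimulated genes had a median log2 ratio of -0.15 over 38 measured members (percentile 0.0300), with 30 below 0, from EPSTI1 at -0.70 to PSMB9 at 0.25, whose second measured probe gave -0.51. The NF-kB list (median -0.05 over 21 members, percentile 19.5, from RELB at -0.52 to TNFAIP2 at 0.54), the microbe-sensing list (-0.03 over 15, percentile 38.4, from TLR3 at -0.77 to TIRAP at 0.68, whose second measured probe gave -0.83) and the antigen presentation list (-0.03 over 15, percentile 32.9, from HLA-G at -0.42 to HLA-C at 0.25) stayed within the range of random lists. Antimicrobial genes were the same in this respect (median -0.02 over 9, percentile 41.6, from CAMP at -0.38 to DMBT1 at 0.30). TLR3 (15.5 against 9.10 units) and HLA-C (11.2 against 13.3 units) were near the floor, with their other probes below it on both arrays. CAMP was also dim (19.2 against 14.7 units).

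Immediate early genes split in direction. FOS was 5.88-fold higher and EGR1 2.53-fold lower, and the 33 measured members had a median log2 ratio of -0.03 (percentile 28.9). Growth factor ligands and feedback genes of the MAPK pathway had a median of -0.17 over 24 members (percentile 0.180), from the plasminogen activator PLAU at -0.85 to the receptor ERBB3 at 0.41. The 18 members above the 75th percentile of all probes had a median of 0.018, with no shift downward, and the call was also lost with the probe of smallest change (-0.092). Targets of TGF-beta, SRF and YAP had a median of -0.13 over 21 members (percentile 0.980), from AMOTL2 at -0.96 to TPM2 at 0.38, and of -0.030 over the 14 members above that higher floor. In the Wnt and stem cell list DKK1 and ID2, an inhibitor of basic helix-loop-helix factors, were 2.69-fold and 2.22-fold lower, while the list's median was -0.03 over 16 members (percentile 33.9).

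The fixed lists of barrier, mucin, enterocyte and epithelial marker genes lay within the central 95% of their random lists. The tight junction and adhesion list had a median log2 ratio of 0.08 over 27 members (percentile 92.6), from MARVELD2 at -0.39 to CLDN3 at 0.55. Mucin and goblet cell genes had a median of -0.03 over 15 (percentile 44.7), from the mucin glycosyltransferase GCNT3 at -0.48 (2860 against 2057 units) to RETNLB at 0.60. RETNLB was near the floor (9.64 against 14.6 units), and its other probe was below the floor on both arrays. Enterocyte genes had a median of -0.01 over 9 (percentile 44.9), from KLF5 at -0.45 to the intestinal transcription factor CDX2 at 0.68. In the epithelial marker list (median 0.13 over 11, percentile 97.2) the transcription factor ELF3 was 2.37-fold higher (277 against 656 units). That list passed above the range of random lists in 5 of 9 alternative settings.

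Lipid genes and the list of short-chain fatty acid and lactate genes were higher by small amounts. The cholesterol and lipid list had a median log2 ratio of 0.15 over 29 members (percentile 99.9), with 23 above 0. Its members at least 2-fold higher were ANGPTL4 and the lipid droplet protein PLIN2 (2.12-fold, 135 against 287 units), neither of which makes cholesterol or fatty acids. The short-chain fatty acid and lactate list had a median of 0.16 over 15 members (percentile 99.3), with CYP1A1, a cytochrome induced through the aryl hydrocarbon receptor, 2.76-fold higher (46.9 against 130 units). CYP1A1 is neither a receptor nor a transporter of these acids, so the list's name does not describe its member at least 2-fold higher. The call on that list was lost in 3 of 9 settings. FFAR2, a receptor for short-chain fatty acids, was below the floor without bacteria and at 30.0 units after incubation, at least 3.27-fold higher.

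Cell cycle lists differed by small amounts and in opposite directions. G2/M genes had a median log2 ratio of 0.10 over 35 members (percentile 99.5), from PLK1 at -0.45 to CENPF at 0.76. DNA replication genes had a median of -0.09 over 30 members (percentile 1.86), from E2F1 at -0.90 to PRIM1 at 0.14, and histone genes had a median of -0.12 over 20 (percentile 2.45), from H2AC8 at -0.96 to H3-3B at 0.27. The replication call was lost in 5 of 9 settings and the histone call in 8 of 9. The p53 and apoptosis list had a median of -0.09 over 26 (percentile 8.04), from the pro-apoptotic BCL2L11 at -0.91 to APAF1 at 0.96, and passed below the range of random lists with the mean of probes (-0.17).

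Reference genes and the lists of markers of other cell types with 3 or more measured members lay within the central 95% of random lists. The 13 measured housekeeping genes had a median log2 ratio of 0.04 (percentile 78.7), from TBP at -0.29 to the transferrin receptor TFRC at 0.44. Leukocyte markers had 4 measured members (median -0.04), from CORO1A at -0.63 to LYZ at 0.03, endothelial markers had 3 (0.02, from PECAM1 at -0.47 to ENG at 0.21), and neural markers had 3 (0.02), among them ENO2. For fibroblasts VIM alone was measured (0.37), and for erythroid cells AHSP alone (-0.46).

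Genes above the floor on 1 array only have a bound in place of a fold. After FFAR2, the genes with the largest lower bounds of increase were FLVCR1, a heme exporter (at least 3.20-fold), ZNF292 (2.84-fold), SEC61A2 (2.82-fold) and the read-through gene DNAJC25-GNG10 (2.80-fold). In the other direction FOXO6 was at least 4.72-fold lower, followed by CHAC1 and by SOCS2, a suppressor of cytokine signalling (2.89-fold), FRAT1 (2.88-fold, with a second probe above the floor after incubation only) and CLCA4-AS1 (2.84-fold). The brighter array was under 41 units for each of these genes. A total of 25 such genes were at least 2-fold higher and 34 at least 2-fold lower by their bound.

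Of the 34 lists with 3 or more measured members, 5 lay above and 9 below the central 95% of their random lists. If genes varied independently, 1.70 lists would be expected outside it by chance. Members of a pathway can vary together between any 2 flasks, so more lists than that may lie outside without an effect of the bacteria. Lists share some genes and were measured on the same 2 arrays, so they are not independent. Among genes named by the rule, the signs of NCL, PSMB9, TIRAP, PRIM1 and RPS15 depended on how the probe of a gene was chosen. Among genes named outside it, that of CPT1A did so too, as did that of ATF4 through a dim probe only.

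**Figure D3:**
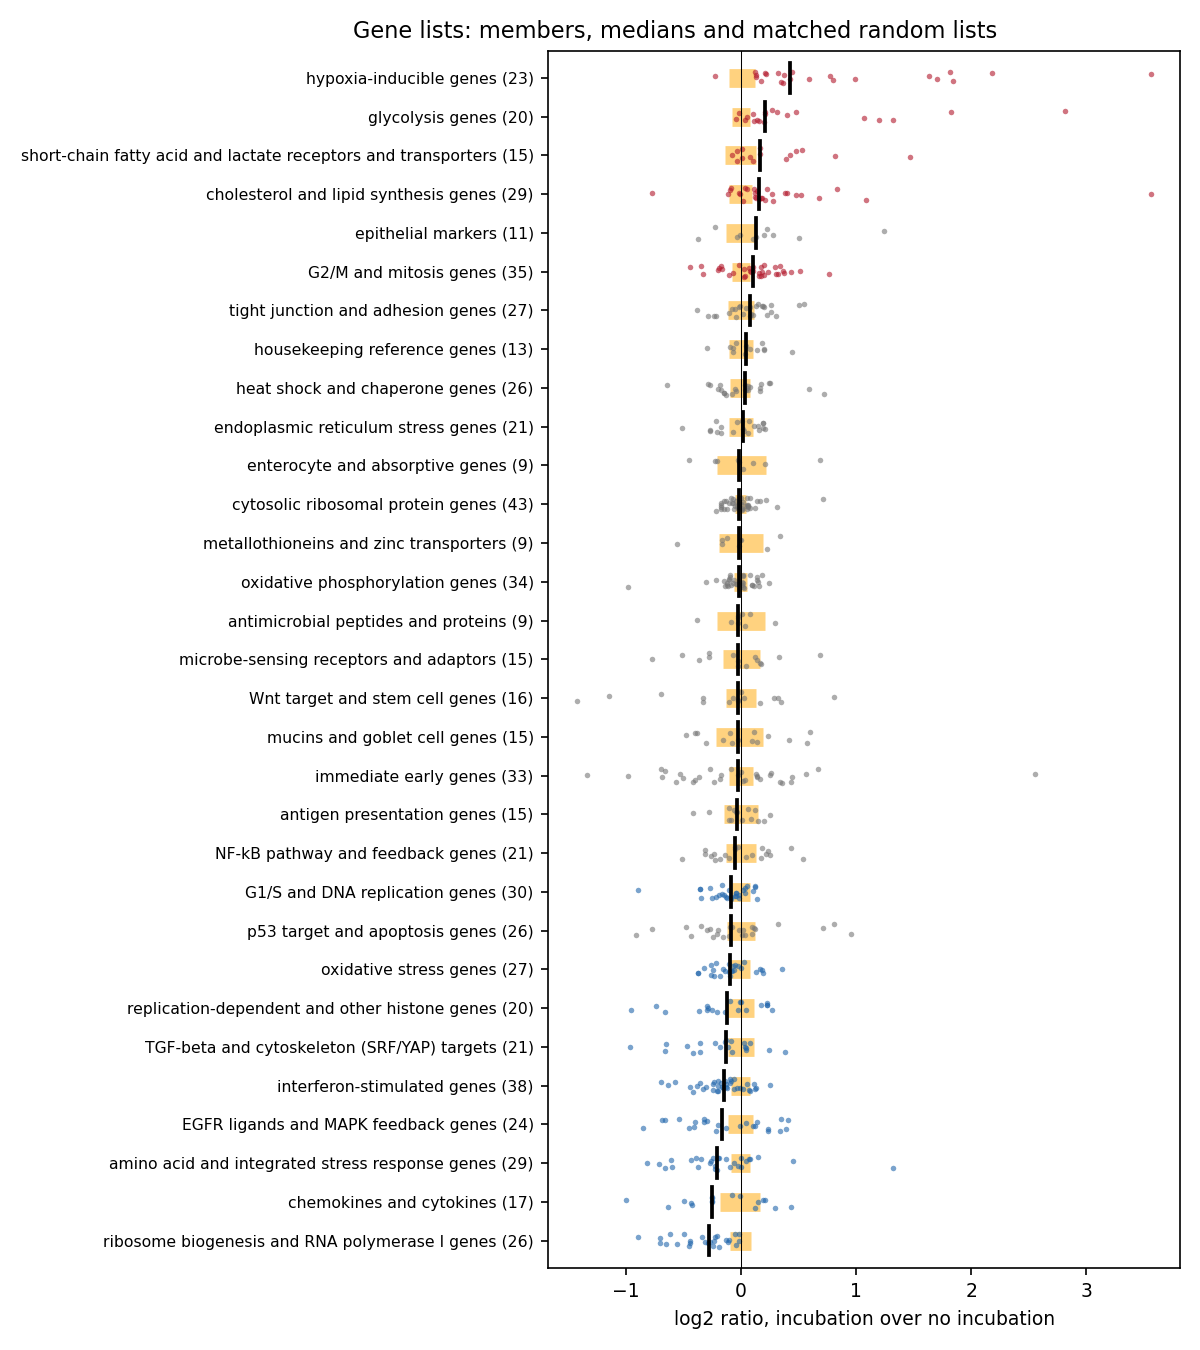
Log2 ratio of incubated over control cells (horizontal axis) for the measured members of each list with 9 or more of them (points, number in brackets), with the list's median (black bar) and the central 95% of medians of 10000 matched random lists (yellow band). Red lists lie above the band and blue lists below it, with hypoxia-inducible genes at the top (median 0.43) and ribosome biogenesis genes at the bottom (-0.28).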

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

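The limit of 100 units on the brighter array was chosen after seeing the data, and the other settings before. No paired analysis was possible because each group has 1 array, and no replicate could be left out. The counts of genes at least 2-fold apart depended on how dim genes were treated. With a floor at the 75th percentile 20 genes were higher and 5 lower, with 50 units added before log2 18 and 1, and with no floor 1024 and 1008. With 100 units or more on the brighter array they were 27 and 6. The other 6 planned settings kept both counts within 1.5 times the main ones, and of the 116 genes called, 104 were shared with the deposited values. Dim probes near background therefore limit the count. The agreement of probes of one gene in sign was 66.7% at the 75th percentile floor. Of 14 lists outside the central 95%, 7 stayed outside under all 9 settings: hypoxia, glycolysis, lipid and G2/M genes above it, and ribosome biogenesis, integrated stress response and interferon-stimulated genes below it. The hypoxia median ranged from 0.35 to 0.44 and the ribosome biogenesis median from -0.33 to -0.22. The EGFR and MAPK list turned to 0.018 at the 75th percentile floor and was -0.092 with the probe of smallest change. The replication list came inside the range at -0.065 (50 units added), -0.070 (deposited values), -0.070 (75th percentile floor), -0.080 (loess) and -0.091 (median centring). The histone list did so at -0.10 (deposited values), -0.12 (60th percentile floor), -0.021 (75th percentile floor), -0.11 (loess), -0.11 (mean of probes), -0.12 (median centring), -0.10 (no floor) and -0.065 (smallest change). The chemokine list did so at -0.096 (50 units added), -0.083 (no floor) and -0.083 (smallest change), the TGF-beta list at -0.030 (75th percentile floor), the oxidative stress list at -0.078 (mean of probes), and the short-chain fatty acid list at 0.043 (75th percentile floor), 0.11 (mean of probes) and 0.077 (smallest change). Epithelial markers passed above the range at 0.12 (50 units added), 0.17 (deposited values), 0.13 (mean of probes), 0.15 (median centring) and 0.13 (smallest change), and p53 genes passed below it at -0.17 (mean of probes). The cause was not tested. Of 746 values under the alternatives of measured genes named by the rule, 57 differed from the main value by more than the spread of genes of like intensity. Of these 57, 45 came with 50 units added before log2. That setting brought 23 of 37 genes named by the rule under 2-fold: ARMC5 had a log2 ratio of -0.49, BDNF -0.42, DKK1 -0.84, SNHG12 -0.95 and FAM13A 0.87. ANGPTL4 was 3.82-fold higher with the mean of probes and 2.14-fold with the probe of smallest change, which also put HK2 at 1.82-fold. Of the 746 values 5 changed sign, all of them less than 2-fold apart: NCL, PSMB9 and TIRAP with the mean of probes, PRIM1 and RPS15 with the probe of smallest change. Among genes named outside the rule, ATF4 (0.24) and CPT1A (-0.39) changed sign with the probe of smallest change. FTL, which was level, did so with the deposited values (0.0099).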

Other observations

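The tests on the intensity trend, other probes, nutrient depletion and FOXO targets were chosen after the result was seen, and those on second lists of hypoxia, MYC and PPAR genes and on background noise before it. The gene groups in the next sentences were also picked after the ratios had been seen, so their percentiles only describe. Probes named for small nucleolar and Cajal body RNA genes were lower as a group. Of 301 such genes on the array 109 were measured, with a median log2 ratio of -0.22, below all 10000 matched random lists. Of the measured genes 29 had ratios above 0. Whether these probes report the mature small RNAs or longer transcripts that hold them was not tested. Genes named as non-coding small nucleolar RNA hosts (the SNHG series and GAS5) had a median of -0.15 over 14 (percentile 1.95), among them SNHG12 (-1.86), SNHG15 (-0.69) and SNHG17 (-0.57). Of 6 measured genes of iron transport and storage (median 0.28, percentile 99.96), the iron importer SLC11A2 was 2.94-fold higher (808 against 2378 units). TFRC had a log2 ratio of 0.44, the iron exporter SLC40A1 0.38, ACO1 0.19 and STEAP3 0.14, and the storage protein FTL was level (15036 against 14999 units). A group of epithelial transcription factors with the splicing regulator ESRP1 (0.52) had a median of 0.51 over 10 members, above all random lists. ELF3 (1.25), GRHL1 (1.14) and OVOL1 (1.13) were highest and KLF5 lowest (-0.45). In this group 4 genes also stand in the fixed lists. GRHL1 and OVOL1 were dim and came under 2-fold with 50 units added. Arrestin-domain and thioredoxin-interacting genes, grouped with the transcription factor MLX (-0.17), had a median of -0.20 over 6 members, inside the range of random lists (percentile 5.70). The members ran from ARRDC4 at -1.36 and TXNIP at -0.68 (2419 against 1513 units) to ARRDC1 at 0.048 and ARRDC3 at 0.43. Probes with no gene name here included 4101 measured ones, of which 42 were at least 2-fold higher and 26 at least 2-fold lower.

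The increase of hypoxia-inducible and glycolysis genes was weighed against artefacts of the arrays. A difference that depends on intensity alone is argued against by the random lists, which were matched on intensity and all lay below the hypoxia median. That median was 0.44 after the loess curve was removed, again above all random lists. Because of the matching, the removal could hardly change the result and adds little. Faulty single probes are argued against for the 18 genes with other measured probes, since these 26 probes had a median of 0.27, with 23 above 0. BHLHE40, KDM3A, ANKRD37, DDIT4, ADM, PFKFB4, ENO2 and SLC2A1 had no second probe, so the test does not cover them. For ANGPTL4 the other probes were higher but well under the brightest. Lower oxygen in the flask with bacteria predicted that further hypoxia genes would be higher. A second list sharing none with the first had a median of 0.34 over 23 members, above all random lists, so the prediction was met. The median was also 0.34 without POFUT4, whose value had been seen. Any other cause that raises hypoxia-inducible genes would raise this list too, so it does not single out low oxygen. For nutrient depletion strong enough to activate ATF4, the integrated stress response list had a median of -0.21, with no rise relative to the control flask. That value was known before depletion was weighed. Depletion in the control flask would also lower the ratio, so the value does not decide the question. With 1 flask each, handling, medium change or cell density may still account for all of the increase, and oxygen was not measured.

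The decrease of ribosome biogenesis and integrated stress response genes was not removed with the intensity trend. The ribosome biogenesis median was -0.28 after loess and both lists stayed below the range of random lists. Those lists were already matched on intensity, so the removal of the trend adds little. Lower MYC-driven transcription is a candidate explanation, raised after MYC itself was seen to be 1.62-fold lower (2236 against 1380 units). A second list of 23 measured MYC targets outside the nucleolus had a median of -0.049, with 8 above 0, inside the range of random lists. The prediction of a median below that range was therefore not met, though a smaller shift stays open. A difference between flasks unrelated to the bacteria could not be tested.

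Most genes at least 2-fold apart were dim, 83 of 116. Background noise of dim probes, of the size seen in silent-gene probes and added to equal levels, gave a median of 5 such genes over 100 draws, from 1 to 11. A simulation of this kind excludes no other noise, such as probe effects that differ between arrays, so how many dim calls may be noise cannot be told apart from real change. Of 8 dim genes with a second measured probe, 6 had the same sign in both, as did 8 of 8 brighter ones.

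ANGPTL4, PDK4, PLIN2 and CPT1A, all known PPAR targets and grouped after their values were seen, were higher by their brightest probes, and PPAR activation might account for them. For CPT1A the probes disagree, since the brightest had a log2 ratio of 0.68, the second -0.39, and the other was at 10.1 units without bacteria and below the floor after incubation. A second list of PPAR targets had a median of 0.080 over 15 members (percentile 89.5), and a list of FOXO targets, another possible explanation, had 0.15 over 16 (percentile 96.7). Both lay inside the central 95% of random lists, so the prediction of a median above it was not met for either, though smaller shifts are not excluded, and the FOXO list shares 5 genes with the fixed lists.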
